A study of Mus musculus with 3 samples.

How the data were processed

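H3K27ac, a histone acetylation found at active promoters and enhancers, was measured by ChIP-seq in MIN6 cells, a mouse insulinoma line used as a beta cell model. Per the labels, Cas9-expressing cells received a guide RNA against Arid1a, single-cell clones were grown, and clones were assigned by PCR genotyping and Western blotting to wild type, Arid1a heterozygous knockout and Arid1a homozygous knockout. Each genotype had 1 library, so there were no replicates, and no comparison carries a test across samples or a p-value.

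Peaks had been called by the authors separately for each library with MACS2 on genome build mm10, after demultiplexing with bcl2fastq, per the submitters' processing notes. The versions of these tools, the aligner, the control sample and the calling threshold are not given in the sources used here. For each peak the deposited lists hold its position, a score, a fold enrichment over the local background, −log10 p, −log10 q and the place of the summit. The score in the deposited lists is 10 times the −log10 q as a whole number for 41489 of 41490 wild-type, all 31365 heterozygous and 34295 of 34298 homozygous peaks. Peak names in the deposited wild-type list carry the tag GAL4, whose meaning is not given in the sources used here, so that which clone served as wild type rests on the labels alone. The fold enrichment of a peak is the authors' own ratio within its library, and the deposited −log10 q depends on the depth of that library. Both were used to describe, rank or filter peaks within a list and not to compare the height of a peak between libraries. Read totals are not given in the sources used here. A summit pile-up and a background were instead solved for each peak from its deposited fold enrichment and −log10 p, with fold taken as pile-up plus 1 over background plus 1 and p as a Poisson tail, to within 0.001 of the deposited −log10 p. Whole-number pile-ups were found for 41489 of 41490 wild-type, 31363 of 31365 heterozygous and 34297 of 34298 homozygous peaks. The lowest background of a list, in reads per position, served as its relative depth, on the assumption, not checked here, that it follows the number of reads used for calling.

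Peaks of the 3 libraries that touched or overlapped were merged into union regions on chromosomes 1 to 19, X and Y, which held all listed peaks. Peaks in repeated or multi-copy sequence were not filtered out. A region was gained in a library relative to another where the first had a peak of at least 1 bp in it and the second had none, and lost in the reverse case. Overlaps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The union was checked against bedtools 2.31.1, and all 52938 regions were identical. Figures were drawn with matplotlib 3.10.9. Shares have Wilson 95% intervals, which cover counting error only and not the difference between clones. Because both knockouts were compared with the same wild-type list, the patterns of presence over the 3 libraries were also set against a log-linear model with 1 sensitivity term per library and 1 term per number of libraries. The overlap of the gained and of the lost sets was also set against the overlap of independent sets.

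Genes came from a table of 21887 protein-coding genes on GRCm38.p6, the assembly of mm10. The table gives the start and end of each gene but not its strand or exons, so that transcription start sites, exons, introns and UTRs are not known here. A region within 1 kb of either end of a gene was therefore called a gene-end region, in place of the promoter class planned before the data were examined, and other regions were classed as inside a gene or intergenic. Each region was assigned to the gene with the nearest end within 100 kb. Nearness does not show that a region regulates a gene.

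The 19 gene lists covered EGF family ligands, ErbB receptors and proximal regulators, MAPK and immediate early response, other receptor tyrosine kinases, beta cell transcription factors, beta cell secretory function, genes normally silent in beta cells, islet progenitor and dedifferentiation genes, alpha cell markers, delta, PP and epsilon cell markers, acinar markers, duct and keratin markers, mesenchymal markers, immune and endothelial markers, neuronal markers, SWI/SNF subunits, cell cycle, YAP and TEAD targets, and housekeeping genes. All 351 entries, 345 of them distinct, matched a symbol of the table. The net balance of a list, gained minus lost over all regions of its members, was placed as a percentile among 10000 random lists matched on the number of regions per gene. A percentile describes these libraries and is not a p-value.

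The genes named for each comparison and direction were the 10 with the most strong one-sided regions. Strong means that the −log10 q of the peak was at or above the median of its list and that the other library had no peak within 1 kb. The 3 strong one-sided regions with the highest fold enrichment, Arid1a, the members of both EGF lists and of the beta cell transcription factor list with a gained or lost region, and up to 4 members of each other list with the most gained plus lost regions were named too. Any other gene was chosen after its values were seen, and the text says so. Peaks within 12.5 kb were also stitched into clusters.

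The steps were tested on simulated data. All 4449 simulated pile-ups were recovered within 0.001, and each of the 7 presence patterns had its planted count among 4350 regions. The sensitivity model gave an observed over expected ratio of 1.01 for the pattern of both knockouts without wild type when nothing was planted, and 1.18 when an excess of 50 percent was planted, so it understates an excess. Of 200 random lists with nothing planted, 5.5% lay outside the central 95% of their matched lists, and a list with planted gains stood at percentile 99.9.

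The alternatives were a −log10 q of at least 5, lists shortened to the length of the shortest by −log10 q or by fold enrichment, an overlap of at least 50% of the shorter peak, a peak within 1 kb counted as shared, a union over the 2 libraries compared, bases in place of regions, leaving out X and Y, merging across gaps of up to 1 kb, gene ends of 3 kb, gene assignment within 50 kb or at gene ends only, and stitching at 5 kb. Taking all sequences in the lists changed nothing, since they hold no others. Added after the data were seen were thinning of the wild-type pile-ups to the background of the knockouts, the same thinning with wild-type peaks under 250 bp dropped and a −log10 p of at least 8.70 required, the value below which 5 percent of knockout peaks lie, thinning with those 2 limits set on all 3 lists and with −log10 p limits of 15, 20 and 30 in place of 8.70, shortening by fold enrichment for the presence patterns, and giving regions inside a gene to that gene.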

Results

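H3K27ac peaks were examined in 3 MIN6 clones, wild type, Arid1a heterozygous knockout and Arid1a homozygous knockout, with 1 library each. Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The series concerns how its loss relates to beta cell regeneration and EGF signalling, and the comparisons ask which acetylated regions differ between the genotypes. With no replicates, every difference below is a difference between single clones.

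The wild-type list held 41490 peaks over 25.1 Mb, the heterozygous list 31365 peaks over 17.5 Mb and the homozygous list 34298 peaks over 20.2 Mb. Median peak widths were 509, 474 and 489 bp, and the authors' fold enrichment within each list had medians of 5.67, 5.81 and 6.31. The recovered background was 2.17 reads per position in wild type, 1.25 times that of the heterozygous library, while the homozygous background was 1.00 times the heterozygous one. Median recovered summit pile-ups were 49, 47 and 54 reads, so that the libraries did not rank alike by the 2 measures. With the highest background in wild type, depth and genotype cannot be separated in the counts against it. The 3 lists merged into 52938 union regions.

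Arid1a itself, on chromosome 4 at 133679008 to 133756769 (mm10), had 5 regions in wild type, 4 in the heterozygous and 6 in the homozygous library. Acetylation near the gene does not check the knockout, because a small edit in the coding sequence need not alter it. The genotypes rest on the PCR and Western blotting that the labels describe.

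In the homozygous library against wild type, the genes with the most strong gained regions were Shc3, an adaptor of receptor tyrosine kinase signalling, with 0 regions in wild type and 6 in the homozygous library, and Sv2c, a synaptic vesicle protein, with 7 and 17. Rad51b, a DNA repair gene, had 1 and 8 regions, and Arid1b, the paralog of Arid1a in the same complex, had 11 and 16. Cpe, which encodes a prohormone-processing carboxypeptidase, had 8 and 12. The genes with the most strong lost regions were Frmd4b, with 21 regions in wild type and 4 in the homozygous library, and Sobp, with 12 and 1. Nfatc2, a calcineurin-regulated transcription factor, had 12 wild-type regions and 0 in the homozygous library, the sialyltransferase gene St6gal1 10 and 0, and Dpysl3 6 and 0. Scgn, which encodes the islet calcium-binding protein secretagogin, had 6 and 3.

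The other genes named for gains were Prrc1 with 1 region in wild type and 4 in the homozygous library, Iqsec3 with 1 and 6, Slc4a1ap with 1 and 4, Ptp4a2 with 5 and 6, and Dntt with 0 and 3. For losses they were Gm30733 with 15 and 1, 1700071K01Rik with 10 and 3, Xxylt1 with 12 and 9, and Zfp169 with 12 and 4. The strongest gained regions by fold within the homozygous list lay near Cyp2d34 on chromosome 15 at 82597150 to 82597493, with a fold of 24.3, near Kif2a on chromosome 13 at 107034229 to 107034790, with a fold of 18.6, and at an end of Gm7030 on chromosome 17 at 36126504 to 36127174, with a fold of 16.7. The strongest lost regions lay inside Camk1d on chromosome 2 at 5379135 to 5379486, with a fold of 19.2 in the wild-type list, 11962 bp from the pluripotency factor gene Klf4 on chromosome 4 at 55514760 to 55515175, with a fold of 18.8, and on chromosome 1 at 148486189 to 148486578, with a fold of 15.9 and no gene within 100 kb. All coordinates are on mm10.

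**Figure D1:**
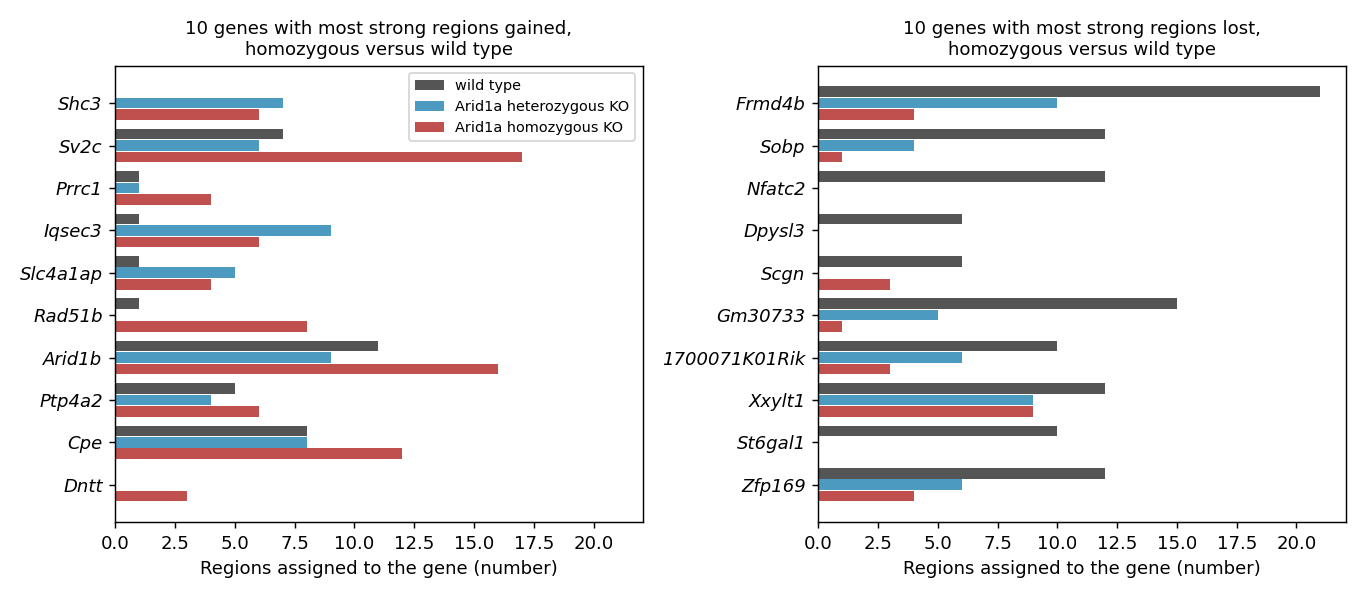
Bars give the number of regions assigned to each gene in the wild-type, heterozygous and homozygous libraries, for the 10 genes with the most strong gained and the 10 with the most strong lost regions of the homozygous library against wild type. Shc3 had 0, 7 and 6 regions and Nfatc2 had 12, 0 and 0.

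Across the genome 8468 of 32635 homozygous regions were gained (25.9%, interval 25.5 to 26.4%) and 15722 of 39889 wild-type regions were lost (39.4%, 38.9 to 39.9%), a ratio of lost to gained of 1.86. The strong sets held 817 gained regions near 587 genes and 2607 lost regions near 1615 genes. Most gained and lost regions were thus not strong, and the region counts given for single genes include them. The cutoff for a strong region was the median −log10 q of the list that held its peak. This median was highest in the homozygous list and lowest in the heterozygous one. Strong gained and strong lost regions were therefore counted at unequal cutoffs, and their numbers do not show which direction prevailed. With all lists shortened to the length of the shortest by −log10 q, which brings both counts together by construction, 8826 regions were gained and 9162 lost. With wild type thinned to the knockout background and a floor of 250 bp and −log10 p of 8.70 for all 3 lists, 7477 were gained and 10899 lost, but with a floor of 15 these were 6380 and 6012, so that their order depended on the floor. Over the alternatives the net count of a named gene changed sign in 90 cases, among them those of Xxylt1, Zfp169, Sv2c, Cxxc5, Stx16, Smad3, Slc16a1, Phlda1, Dpf3, Foxa2, Erbb3, Cdh2, Zeb2, Slc2a2 and Spring1 in at least 1 comparison.

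Of the fixed lists, the genes normally silent in beta cells and the MAPK and immediate early genes stood at the upper end in the homozygous library. The silent genes had 34 gained and 17 lost of 94 regions, at percentile 99.8 of matched random lists, although 6 of the members had more gained regions, 6 more lost and 4 as many of each. Despite the name of the list, 12 of its 16 members had regions in wild type, 37 in all, and 8 had a wild-type peak at a gene end. Members with more regions than in wild type included the hexokinase gene Hk1, with 2 regions in wild type and 9 in the homozygous library, the chemokine gene Cxcl12, with 0 and 6, and the lactate transporter gene Slc16a1, with 10 and 13. Smad3, which transmits TGF-beta signals, was opposite, with 5 and 2. Of the gained regions, 1 at Slc16a1 and none at Hk1 or Cxcl12 was strong. The MAPK list had 34 gained and 26 lost of 143 regions, at percentile 98.7, and 12 of its members had more gained than lost regions while 5 had more lost. Dusp4 had 5 and 6 regions, Dusp5 7 and 8, Phlda1 8 and 9, and Jun 8 and 6. Fos, with 7 and 11 regions, and the sprouty gene Spry4, with 0 and 3, were chosen after their values were seen, and without Fos the list stood at 97.2, inside the central 95%. The list had 94 regions in wild type and 94 in the heterozygous library.

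SWI/SNF subunit genes had 25 gained and 16 lost of 104 regions in the homozygous library, at percentile 98.1, and 7 members had more gained regions, 6 more lost and 13 as many of each. Of the 25 gains 7 were at Arid1b and 6 at Smarca2. Smarca2 had 11 regions in wild type and 15 in the homozygous library, Smarca4 3 and 6, and Dpf3 6 and 4. Immune and endothelial markers stood at the lower end, at percentile 1.80, with 1 gained and 11 lost of only 20 regions, among them 2 lost at Cd79a. Thus 4 of 19 lists lay outside the central 95%, where 0.95 were to be expected by chance. None did with lists of equal length. The silent genes then stood at percentile 91.35, the MAPK list at 89.985, SWI/SNF at 82.8 and immune markers at 3.81. The random lists were not matched on place. A peak at a gene end in all 3 libraries was found for 23 of 26 SWI/SNF and 22 of 26 MAPK members, against 10020 of all 21887 genes. What this does to the percentiles was not tested.

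EGF family ligand genes had 4 gained and 9 lost of 25 regions in the homozygous library, at percentile 32.5. Tgfa had 4 regions in wild type and 1 in the homozygous library, betacellulin (Btc) 4 and 2, Hbegf 6 and 4, and Nrg2 3 and 2. Nrg3 had 0 and 2, but a net loss of 2 when regions inside a gene were given to that gene, and Nrg4 had 2 and 3. ErbB receptors and proximal regulators had 5 gained and 19 lost of 67 regions, at percentile 23.9. The ErbB inhibitor gene Lrig1 had 6 and 1 regions, the phosphatase gene Ptpn11 9 and 4, Erbb3 3 and 1, Plcg1 5 and 3, and Gab2 5 and 3. Egfr had 0 and 1, and Errfi1 4 and 5. The ligands had 7 gained and 5 lost regions and the ErbB list 9 gained and 9 lost when lists had equal length, and Ptpn11 and Plcg1 then turned to a net gain of 1 each.

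Beta cell transcription factor genes had 12 gained and 40 lost of 120 regions in the homozygous library, and 15 of the 19 had more lost than gained regions. Isl1 had 10 regions in wild type and 5 in the homozygous library, Myt1 7 and 2, Foxa2 10 and 8, Nkx6-1 7 and 5, Rfx6 6 and 4, and Mafa 3 and 2, while Pdx1 alone had more, with 2 and 4. The percentile of 16.9 lay within that of random lists. Equal list lengths gave 14 gained and 20 lost regions, and Isl1, Nkx6-1 and Rfx6 turned to net gains of 1, 1 and 2. Secretory genes stood at percentile 75.6, with 40 gained and 57 lost of 196 regions. Of the members 12 had more gained regions, 14 more lost and 9 as many of each. The zinc transporter gene Slc30a8 had 14 and 6 regions, the gap junction gene Gjd2 10 and 2, and the prolactin receptor gene Prlr 8 and 1, while the insulin genes Ins1, with 4 and 4, and Ins2, with 2 and 3, were chosen after their values were seen.

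The remaining lists lay within the central 95% in the homozygous library against wild type. Alpha cell markers stood at percentile 56.9, with Gcg at 0 and 3 regions and Irx1 at 4 and 0. Duct and keratin markers stood at 87.4, and Cdh1, which encodes E-cadherin, had 1 and 8 regions, with none of the gained ones strong. Delta, PP and epsilon markers stood at 4.08 with 6 regions in all, acinar markers at 85.7, and mesenchymal markers at 3.02, where Zeb2 had 8 and 1. Islet progenitor genes stood at 83.7, neuronal markers at 89.955, other receptor tyrosine kinases at 8.92, cell cycle genes at 86.6, YAP and TEAD targets at 58.8 and housekeeping genes at 79.0. Some of these lists left the central 95% under another setting. Other receptor tyrosine kinases reached 0.475, mesenchymal markers 0.915, duct and keratin markers 99.795 and cell cycle genes 97.595.

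**Figure D2:**
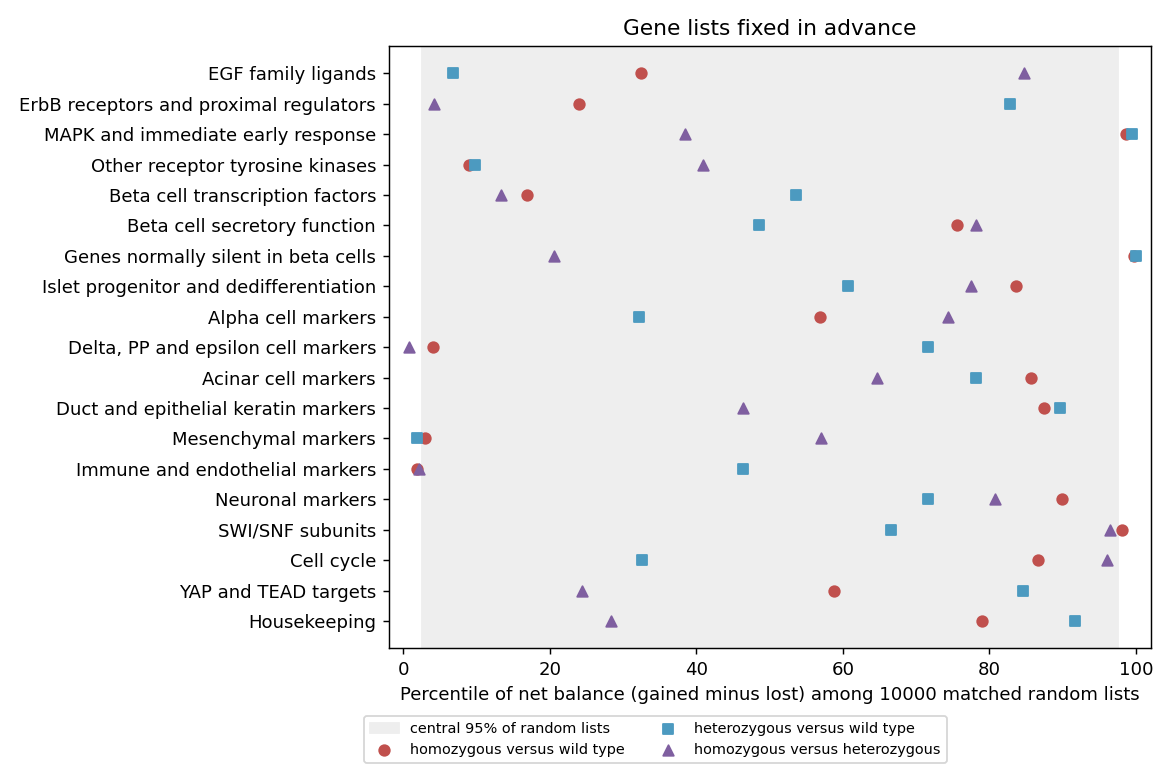
Each point is the percentile of a list's net balance, gained minus lost regions, among 10000 matched random lists, for the 3 comparisons, and the shaded band is the central 95%. The genes normally silent in beta cells stand at 99.8 and 99.99 in the homozygous and heterozygous libraries against wild type.

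In the heterozygous library against wild type, Unc5b, a netrin receptor gene, had 3 regions in wild type and 17 in the heterozygous library, Eva1a had 0 and 10, Iqsec3 1 and 9, and Shc3 0 and 7. Pcgf5 had 2 and 7, Pofut2 4 and 9, Cxxc5 11 and 16, Ly86 5 and 7, Smad3 5 and 7, and Stx16 13 and 14. Losses were led by Gm30733, with 15 and 5 regions, and Galnt14, with 8 and 0. Nfatc2 had 12 and 0, the adenylate cyclase gene Adcy5 9 and 0, St6gal1 10 and 0, Vwa5b1 13 and 1, Tmeff2 7 and 0, and Dpysl3, Scgn and Adgrd1 6 and 0 each. The strongest gained regions lay at an end of Tpbg on chromosome 9 at 85842536 to 85842922, with a fold of 17.3 in the heterozygous list, near Zfp869 on chromosome 8 at 69728530 to 69728866, with a fold of 16.1, and at the Cyp2d34 region, with a fold of 15.7. The strongest lost regions lay at Mpzl3 on chromosome 9 at 45054758 to 45055819, with a fold of 15.4 in the wild-type list, near Ehhadh on chromosome 16 at 21728068 to 21728508, with 15.1, and at Pcdhga5 on chromosome 18 at 37694335 to 37694861, with 14.8.

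Of 29237 heterozygous regions 6252 were gained (21.4%, interval 20.9 to 21.9%), and 16904 of 39889 wild-type regions were lost (42.4%, 41.9 to 42.9%), a ratio of lost to gained of 2.70. The strong sets held 771 gained regions near 493 genes and 2702 lost regions near 1690 genes. Lists of equal length by −log10 q gave 8234 gained and 9242 lost regions, and with wild type thinned and the same floors for all lists 5456 were gained and 11881 lost at 8.70 and 4074 and 7165 at 15.

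The receptor gene Egfr, on chromosome 11 at 16752203 to 16913907, had 0 regions in wild type, 6 in the heterozygous and 1 in the homozygous library. A heterozygous region at 16752074 to 16752661 covered an end of the gene with a fold of 5.00, 3 lay inside the gene, at 16769661 to 16770036, 16809580 to 16809779 and 16810246 to 16810748, and 2 lay outside it, at 16701179 to 16701791 and 16702235 to 16702546. The homozygous region overlapped that at 16810246. The folds within the heterozygous list were 2.93 to 5.00, below its median of 5.81, and none of the 6 peaks was strong.

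**Figure D3:**
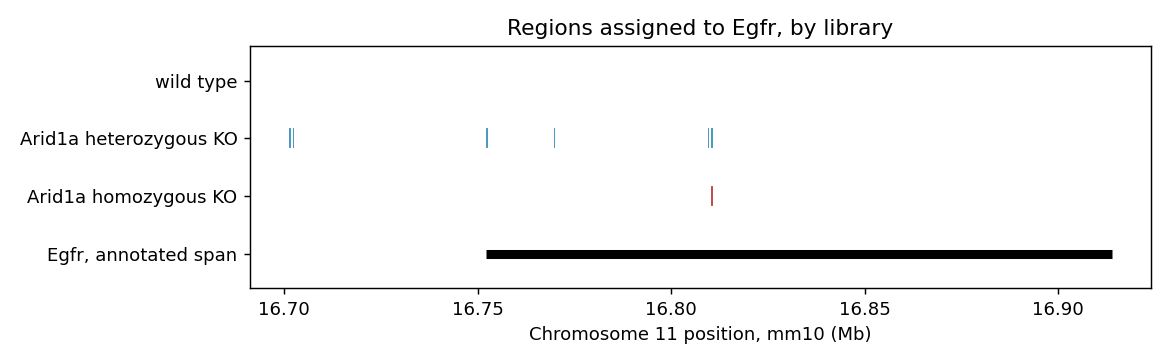
Bars mark the positions, in Mb on chromosome 11 (mm10), of the regions assigned to Egfr in each library, above the annotated span of the gene. There were 0 regions in wild type, 6 in the heterozygous and 1 in the homozygous library.

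Among the other EGF pathway genes more regions were lost than gained in the heterozygous library, except for the ErbB list with lists of equal length. Ligand genes had 1 gained and 12 lost of 25 regions, at percentile 6.82. Over all settings the percentile of the ligand list ranged from 1.79 to 19.7, so that its place within the central range of random lists depended on the setting. Btc had 4 regions in wild type and 0 in the heterozygous library, Tgfa 4 and 1, and Nrg2 3 and 0. The ErbB list had 15 gained and 22 lost regions, at percentile 82.9, and 6 of the 15 were those of Egfr. Lrig1 had 6 and 1 and Ptpn11 9 and 2, while Errfi1 had 4 and 6 and Eps15 1 and 3. The ErbB list had 17 gained and 8 lost regions and the ligands 3 and 7 when lists had equal length.

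Silent genes stood at percentile 99.99 in the heterozygous library, with 30 gained and 13 lost of 94 regions, and 9 members had more gained regions, 3 more lost and 4 as many of each. The growth factor receptor gene Pdgfra and the transcription factor gene Nfib each had 1 region in wild type and 6 in the heterozygous library, against 0 each in the homozygous one. The MAPK list stood at percentile 99.5, with 26 gained and 26 lost of 143 regions. Dusp4 had 5 and 7 regions, while Phlda1 had 8 and 3, Egr2 7 and 2, and Spred2 7 and 4. Dusp6, with 2 and 6, was chosen after its values were seen. Mesenchymal markers stood at 1.86, with 1 gained and 17 lost of 28 regions, among them Zeb2 at 8 and 3 and Cdh2 at 6 and 1. With lists of equal length the silent genes stood at 99.98, the MAPK list at 93.0 and mesenchymal markers at 12.05. Thus 1 list rather than 3 then lay outside the central 95%. Under other settings alpha cell markers reached 0.48 and EGF family ligands 1.79, which also lie outside it.

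Beta cell transcription factor genes had 17 gained and 42 lost regions in the heterozygous library, at percentile 53.6, and 11 had more lost than gained regions. Neurod1 had 2 regions in wild type and 5 in the heterozygous library, Isl1 10 and 5, Foxa2 10 and 5, Myt1 7 and 2, and Mafa 3 and 1. This list had 30 gained and 22 lost regions when lists had equal length, and Isl1, Nkx6-1, Pax6 and Foxa1 turned to net gains. Secretory genes had 18 gained and 61 lost of 196 regions, at percentile 48.5, with Gjd2 at 10 and 3 and Prlr at 8 and 1. The receptor tyrosine kinase gene Ntrk3 had 19 regions in wild type and 0 in the heterozygous library, and Ntrk2 12 and 5, within a list at percentile 9.75. Of the 19 lost regions at Ntrk3, 1 was strong. Cell cycle genes stood at 32.5, and Ccnd2, which encodes cyclin D2, had 6 and 0 regions.

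In the homozygous against the heterozygous library, whose lowest recovered backgrounds were alike, the genes with the most strong gained regions were Vwa5b1, with 1 region in the heterozygous and 10 in the homozygous library, and the GABA transaminase gene Abat, with 0 and 8. Galnt14 had 0 and 7, Gm46240 0 and 7, Ctsb 2 and 8, Spring1 1 and 5, Tacc2 5 and 10, Sdk1 5 and 8, Dtnb 10 and 14, and Ankrd33b 7 and 11. Those with the most strong lost regions were Rbm19, with 12 and 1, Unc5b, with 17 and 3, and Crtac1, with 8 and 0. Frmd4b had 10 and 4, Gtf3a 8 and 4, Capn9 7 and 1, Shisa9 7 and 0, Cplx2 8 and 3, Sh3pxd2a 9 and 4, and Sash1 5 and 0. The strongest gained regions lay at the histone gene H2bc1 on chromosome 13 at 23933698 to 23934050, with a fold of 18.9 in the homozygous list, near Lmo1 on chromosome 7 at 109115249 to 109115966, with 18.8, and at the Kif2a region. The strongest lost regions lay near Mog on chromosome 17 at 37028704 to 37029334, with a fold of 17.99 in the heterozygous list, at the Zfp869 region, and near Ear10 on chromosome 14 at 43925271 to 43926067, with 15.6.

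Of 32635 homozygous regions 11460 were absent from the heterozygous library (35.1%, interval 34.6 to 35.6%), and 8062 of 29237 heterozygous regions were absent from the homozygous one (27.6%, 27.1 to 28.1%). Lists of equal length by −log10 q, which bring both counts together by construction, gave 9395 and 8723. Median recovered summit pile-ups were 54 reads in the homozygous and 47 in the heterozygous library. Differences between the libraries other than genotype thus cannot be separated from it in these counts. SWI/SNF subunit genes had 36 gained and 11 lost of 104 regions, at percentile 96.45, with Smarca2 at 7 regions in the heterozygous and 15 in the homozygous library and Arid1b at 9 and 16. Cell cycle genes had 22 gained and 3 lost, at percentile 96.1, with Ccnd2 at 0 and 8 and the cyclin D1 gene Ccnd1 at 0 and 2. Ligand genes had 7 gained and 1 lost, at percentile 84.8, and the ErbB list 6 gained and 13 lost, at 4.14. Secretory genes stood at 78.2, with the glucose transporter gene Slc2a2 at 1 and 8 and the potassium channel regulatory subunit gene Abcc8 at 8 and 14, and beta cell transcription factor genes at 13.3. Outside the central 95% were delta, PP and epsilon markers at 0.725, with 0 gained and 3 lost of 6 regions, and immune and endothelial markers at 2.18, with 2 gained and 8 lost of 20.

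Shc3 and Iqsec3 were named for gains, and Nfatc2, Dpysl3, Scgn, St6gal1 and Gm30733 for losses, in both comparisons with wild type. In all, 1671 regions were called in both knockouts and not in wild type, and 12241 in wild type alone. Independent gained sets would share 1000.1 regions over all regions, or 4057 over the 13049 regions without a wild-type peak. Neither number is a chance level for the 1671. All regions include those with a wild-type peak, which cannot be gained. The 13049 hold only regions called in at least 1 knockout, so that the sizes of the gained sets fix their overlap. A model in which the libraries differed only in sensitivity gave 1777. Independent lost sets would share 5020.3 or, over the 39889 wild-type regions, 6663, and the model gave 12348. Observed over expected from the model was 0.940 for both knockouts without wild type and 0.991 for wild type alone. The wild-type term of the model is fitted to both counts, so that they deviate from it by the same number of regions. The ratios are therefore not separate checks. Part of the overlap between the comparisons may thus come from the shared wild-type list. The first ratio was 1.18 with lists of equal length by fold enrichment, so that its side of 1 depended on how lists were shortened.

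**Figure D4:**
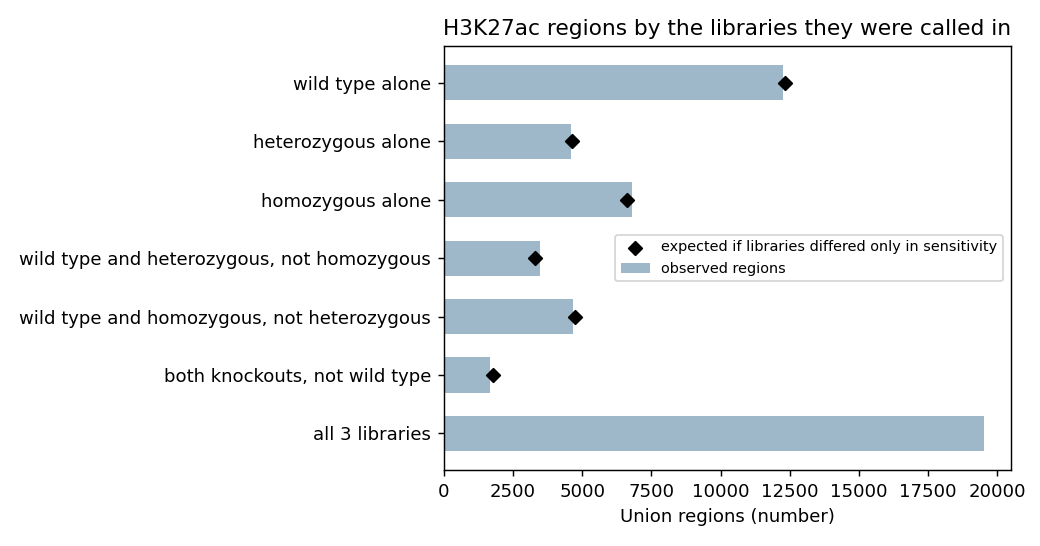
Bars give the number of union regions called in each combination of the wild-type, heterozygous and homozygous libraries, and diamonds the number expected if the libraries differed only in sensitivity. The 1671 regions of both knockouts lie below the expected 1777, and the 12241 of wild type alone close to the expected 12348. The model makes both deviate by the same number of regions.

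All 3 libraries shared 19504 regions (36.8%), of which 58.8% lay at a gene end, with a median width of 819 bp. Regions called in 1 library were narrower and mostly away from gene ends, with 10.4% of the wild-type, 9.02% of the heterozygous and 9.06% of the homozygous ones at a gene end. Widths are those of merged regions, which a merge over more libraries can only widen, and a wider region reaches a gene end more easily. Sharing of peaks followed their strength. Of the homozygous peaks in the lowest quartile of −log10 q 45.0% overlapped a wild-type peak, and of those in the highest 98.9%. For wild-type peaks against the homozygous list the shares were 28.4% and 96.0%, and against the heterozygous list 22.2% and 96.6%.

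**Figure D5:**
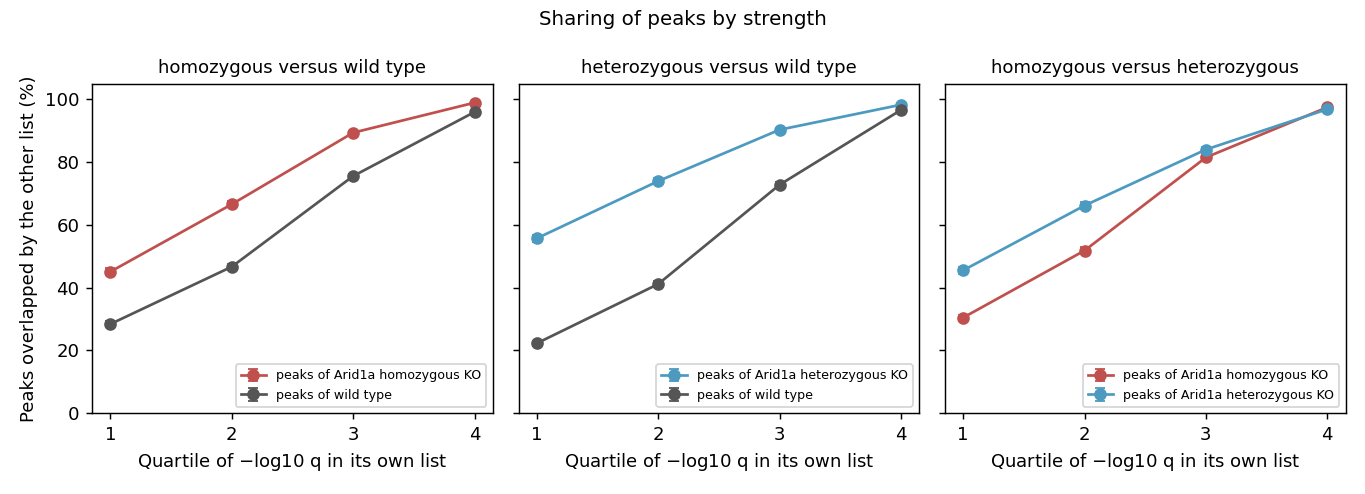
Points give the percent of peaks overlapped by a peak of the other list, by quartile of −log10 q within their own list, with Wilson 95% intervals, for the 3 comparisons. Sharing was 98.9% in the highest quartile of homozygous peaks against wild type and 45.0% in the lowest.

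Gained and lost regions lay at gene ends less often than shared ones. In the homozygous library against wild type 9.74% of gained (interval 9.13 to 10.4%), 12.6% of lost and 51.0% of shared regions lay at a gene end, and in the heterozygous library 9.95%, 12.6% and 53.0%. Among gained regions of the homozygous library 49.9% lay inside a gene and 40.4% between genes. Of 21887 genes, 10020 had a peak at an end in all 3 libraries. Against wild type 308 genes gained and 962 lost their end peaks in the homozygous library, and 268 gained and 1001 lost them in the heterozygous one.

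The largest peak cluster in every library was the histone gene cluster on chromosome 13 at 23517841 to 23593787, where peaks covered 18108 bases in wild type, 10654 in the heterozygous and 15127 in the homozygous library. The cluster at Tnrc6a on chromosome 7 had 41.1% of its wild-type bases in the homozygous and 104.8% in the heterozygous library, and that at Tns3 on chromosome 11 had 83.1% and 46.6%. The cluster at Wars and Wdr25 on chromosome 12 had 129% in the homozygous library. These 3 were chosen from the 20 clusters with the most wild-type bases after their values were seen. Over all 20 the median was 83.1% in the homozygous and 73.9% in the heterozygous library, against 80.5% and 69.7% of the wild-type bases over all clusters. Clusters in repeated sequence were not filtered out. No cluster among the 20 was absent from a knockout. The differences were spread over chromosomes 1 to 19 and X, with 11.7% (chromosome 11) to 19.6% (chromosome 14) of a chromosome's union regions gained and 25.8% (chromosome 19) to 32.0% (chromosome 2) lost in the homozygous library, and 8.84% (X) to 15.1% (chromosome 14) gained and 26.7% (chromosome 19) to 34.9% (chromosome 1) lost in the heterozygous one. Chromosome Y, with only 40 regions, is left out of these ranges, and 22.5% of its regions were lost in the homozygous library.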

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

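The thinned wild-type lists, the lists of equal length by fold enrichment for the presence patterns and the assignment of regions inside a gene to that gene were chosen after the data were seen. No paired analysis was possible because each genotype had 1 library. The recovered background differed between wild type and the knockouts and limits every count against wild type, and the single clones leave the spread between clones of a genotype unmeasured. More regions were lost than gained against wild type under every setting run for these counts except, in the homozygous library, dropping narrow and weak peaks from the thinned wild-type list alone and floors of 15, 20 and 30 for all lists, and the sizes depended on list length. Regions lost from the homozygous library numbered 9162 with lists of equal length by −log10 q and 9641 with wild type thinned and its narrow and weak peaks dropped, and from the heterozygous library 9242 and 10393, since both settings shorten the wild-type list, the second by a filter on that list alone. With wild type thinned and all lists at a −log10 p of at least 15 and 250 bp, 6012 regions were lost from the homozygous library and 4074 gained in and 7165 lost from the heterozygous one. At 20, regions gained and lost numbered 5482 and 4028 in the homozygous and 3109 and 5338 in the heterozygous library, and at 30 they numbered 4554 and 2058, and 1975 and 3564, since fewer peaks of every list pass a higher floor. Regions gained in the heterozygous library numbered 10082 with lists of equal length by fold enrichment. A stricter −log10 q, an overlap of 50%, a union of the 2 lists compared, a peak within 1 kb counted as shared and leaving out X and Y kept every gained and lost count within 1.5 times.

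For the presence patterns, observed over expected was 0.967 for wild type alone and 1.02 for wild type and homozygous with lists of equal length by −log10 q. With lists of equal length by fold enrichment it was 1.18 for both knockouts without wild type, 1.07 for wild type alone, 0.871 for wild type and heterozygous and 0.958 for wild type and homozygous. With wild type thinned and its narrow and weak peaks dropped it was 1.09 for wild type and heterozygous. The cause of these shifts was not tested. Within 3 kb of a gene end, 16.6% of gained, 18.7% of lost and 56.6% of shared regions lay in the homozygous comparison with wild type and 15.6%, 18.7% and 58.5% in the heterozygous one, since the window is wider. With lists of equal length by −log10 q the shares within 1 kb were 11.9%, 14.7% and 55.9%, and 12.3%, 14.8% and 56.0%. Gained and lost regions stayed below shared ones in each of these settings. Cluster medians moved to 87.5% and 69.7% with stitching at 5 kb.

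Lists outside the central 95% in the homozygous library against wild type numbered 2 with genes assigned within 50 kb, 0 with lists of equal length by −log10 q and 1 with wild type thinned and its narrow and weak peaks dropped. In the heterozygous library against wild type the number was 1 with lists of equal length by −log10 q. In the homozygous against the heterozygous library it was 1 with gene-end regions only, 1 with lists of equal length by −log10 q and 1 with a peak within 1 kb counted as shared. Over all settings the silent genes ranged from percentile 91.35 to 99.96 in the homozygous and from 99.94 to 100 in the heterozygous library against wild type, and the MAPK list from 89.985 to 99.8 and from 93.0 to 99.9. Of the list percentiles under other settings 292 stayed on the same side of the bounds of the central 95% and 28 crossed one.

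Net counts of single genes, gained minus lost, rested on few regions. Under other settings 2009 of those that were not 0 kept their sign, 502 moved to 0 and 90 changed sign. Genes with a net count of 0 were not followed, so that moves away from 0 are not counted. With genes assigned within 50 kb, the net counts that changed sign were, in the homozygous library against wild type, -1 for Phlda1, 1 for Tead1 and 2 for Cdh2 and Foxa2. They were -1 for Glis3 and Pabpc1 and 1 for Nkx2-2 and Xxylt1 in the heterozygous library against wild type. They were -1 for Cxcl12 and Dtnb and 1 for Tead1, Ywhaz and Zfp169 in the homozygous against the heterozygous library. With lists of equal length by −log10 q, the net counts that changed sign were, in the homozygous library against wild type, 1 for Cdh2, Ero1b, Isl1, Nkx6-1, Plcg1, Ptpn11 and Smad3 and 2 for Rfx6 and Spring1. They were 1 for Ankrd33b, Capn9, Erbb3, Foxa1, Pax6, Plcg1, Slc16a1, Sox11, Sv2c and Zeb2, 2 for Crtac1, Isl1 and Ywhaz, 3 for Nkx6-1 and 4 for Elavl4 in the heterozygous library against wild type. They were -3 for Pax6 and -2 for Stx16 in the homozygous against the heterozygous library. With wild type thinned and its narrow and weak peaks dropped, the net counts that changed sign were, in the homozygous library against wild type, 1 for Cdh2, Cxxc5, Dpf3, E2f2, Foxa2, Krt7, Nkx6-1, Ptprn2 and Ywhaz and 2 for Isl1, Map2, Pax6, Rfx6 and Spring1. They were 1 for Erbb3, Gtf3a and Pax6, 2 for Elavl4, Nkx6-1, Slc16a1, Sv2c and Ywhaz and 3 for Isl1 in the heterozygous library against wild type. With gene-end regions only, the net counts that changed sign were, in the homozygous library against wild type, -1 for Cdk1 and Fgfr2 and 1 for Ero1b and Krt7. They were -1 for Amotl2 and Etv1 and 1 for Erbb3, Slc2a2 and Xxylt1 in the heterozygous library against wild type. They were -1 for Fgfr2, Gata4 and Slc2a2 and 1 for Bicra, Shc3 and Sox11 in the homozygous against the heterozygous library. With regions inside a gene given to that gene, the net counts that changed sign were, in the homozygous library against wild type, -2 for Nrg3. They were -20 for Rbfox3, -5 for Nrg3 and -2 for Glis3 in the heterozygous library against wild type. They were -2 for Dpf3, 1 for Rbfox3, 2 for Ror1 and 4 for Glis3 in the homozygous against the heterozygous library. With a peak within 1 kb counted as shared, the net counts that changed sign were, in the heterozygous library against wild type, -1 for Krt8 and 1 for Bicra. They were -1 for Pax6 and Stx16 and 1 for Nkx2-2 in the homozygous against the heterozygous library. The cause of these sign changes was not tested.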

Other observations

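The tests on thinned wild-type lists with narrow and weak peaks dropped, from wild type alone or from all lists, and the tests of the MAPK list on such a thinned list and of its chance share under other settings, were chosen only after the results were seen, and so was the grouping of genes in the next paragraph.

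Some genes were all or none between libraries. Of genes with at least 5 regions in each of the other 2 libraries, 15 had none in the homozygous library, among them Crtac1, with 11 regions in wild type and 8 in the heterozygous library, Spock1, with 8 and 9, the synaptotagmin gene Syt9, with 8 and 7, Elmo1, with 8 and 6, and the Wnt co-receptor gene Lrp5, with 7 and 6. In the heterozygous library 11 such genes had none, among them the receptor tyrosine kinase genes Ntrk3, with 19 regions in wild type and 10 in the homozygous library, and Ror2, with 6 and 7, the homeobox gene Meis2, with 8 and 5, and Ccnd2, with 6 and 8. Only Shc3 was missing from wild type alone. Regions at 41 genes were called in wild type only, with at least 5 each, against 3 genes in the heterozygous and 3 in the homozygous library only. With lists of equal length the genes missing from 1 library were 3 for wild type, 5 for the heterozygous and 4 for the homozygous library, and those present in 1 library only were 13, 5 and 5.

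More regions were lost than gained against wild type in both knockouts, with ratios of 1.86 and 2.70. Thinning the wild-type summits to the knockout background left ratios of 1.79 and 2.61 and decides nothing, because it removed only 1.20% of wild-type peaks. The bound set beforehand was thus wrong. A call also needs a width, which thinned summits do not change, but whether this is why so few peaks were removed was not tested. Dropping narrow and weak peaks from the thinned wild-type list alone gave 0.909 and 1.31 and decides nothing either, since that filter without any thinning already gave 1.16 and 1.68. With the same floor for all 3 lists the ratios were 1.46 and 2.18, the heterozygous one above and the homozygous one level with the 1.46 between the knockouts, but with stricter floors the homozygous ratio fell to 0.939, 0.738 and 0.448, and the heterozygous ratio of 1.72 to 1.79 lay below the 1.81 to 3.85 between the knockouts at those floors. In the heterozygous library more regions were lost than gained at each of these floors, and only its side of the ratio between the knockouts depended on the floor. That ratio was taken as a bound after the results were seen. It compares 2 genotypes, so that it gives no level to be expected from depth alone. Wild-type depth as the whole cause thus stays open, and so does whether loss of Arid1a lowers the number of acetylated regions.

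Regions of 1 gene were lost together, and 51 of the 1882 genes with at least 5 wild-type regions had all of them absent from both knockouts, among them Nfatc2, St6gal1, Dpysl3 and Adgrd1. Peaks missed independently near the calling threshold, at rates set by strength alone, are argued against. In 1000 shuffles of the patterns among wild-type regions of like −log10 q there were 3.73 such genes on average and 13 at most. The shuffles did not match on place. Of the regions called in wild type alone 10.4% lay at a gene end, against 58.8% of those in all 3 libraries. Deletion of a large chromosome segment at most of these genes is argued against as well. Of the 1948 wild-type regions 200 kb to 1 Mb away, 55.2% (interval 53.0 to 57.4%) were kept in the homozygous library and 53.8% in the heterozygous one. Of all 39889 wild-type regions 24167 and 22985 were kept, which are larger shares. The interval takes regions as independent, although regions of 1 gene were lost together, so that it may be too narrow. The shares near the 51 genes are pooled, so that a large deletion at some of them stays open, and so do smaller deletions. Clone differences unrelated to genotype stay open, since genes missing from 1 library alone numbered 1 for wild type, 11 for the heterozygous and 15 for the homozygous library, but 3, 5 and 4 with lists of equal length, and full loss of Arid1a would also give genes missing from the homozygous library alone. Wild-type depth stays open too, since the 51 genes and the shuffles rest on the full lists. Genes called in wild type only, with at least 5 regions each, numbered 41 on the full lists. With lists of equal length they numbered 13, against 5 in the heterozygous and 5 in the homozygous library only. A coordinated loss of acetylation at these genes after loss of Arid1a is a hypothesis that more clones per genotype would test.

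The ligand and receptor genes of the EGF pathway did not stand above their random lists in both knockouts. The silent genes did, at percentiles 99.8 and 99.99, but at 91.35 in the homozygous library with lists of equal length. Among them only Oat, Cxcl12 and Maf had more gained than lost regions in both comparisons. Oat and Maf were chosen after their values were seen. Hk1 and Slc16a1 had more gained regions only in the homozygous library, Pdgfra and Nfib only in the heterozygous one. Both comparisons share the wild-type list, and what this adds was not tested. The MAPK and immediate early list also stood above its random lists in both, at 98.7 and 99.5. A single gene as the whole cause is argued against, because the lowest percentile with 1 member left out was 97.2, without Fos, although that lies inside the central 95%. Chance among 19 lists stays open, since the share of matched random lists that reached its balance in both comparisons was 0.1%, under the bound of 0.26% set beforehand, but 1.95% with lists of equal length, so that a bound on the full lists alone was wrong. Wild-type depth stays open, since the lower of the percentiles was 95.07 with wild type thinned and its narrow and weak peaks dropped and 89.985 with lists of equal length. The list had 94 regions in wild type and 94 in the heterozygous library, fewer than in the homozygous one, and that acetylation near these genes may be spared is a hypothesis that several clones per genotype at equal depth would test.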
